A study of Rattus norvegicus with 8 samples.

How the data were processed

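RNA from 8 cultures of rat neonatal ventricular cardiomyocytes was sequenced as total RNA with an Illumina TruSeq RNA kit on a HiSeq 2000, per the labels. The 4 groups, normoxia or ischemia with DMSO or eugenol, had 2 libraries each, assigned from the labels. The deposited tables name their columns by code, and the table titles allowed only 1 assignment of these codes to the groups.

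The authors deposited 5 tables, each for 1 pair of groups and each holding only genes with an unadjusted p under 0.05. The read counts were deposited per gene, and the submitters' processing notes name HISAT2, StringTie 1.3.3b, edgeR and DESeq2 without roles or order. The normalized signal was made by the authors by dividing the count by 1 size factor per library and table. The FPKM values were deposited by the authors per kilobase of gene length and per megaread, and their ratio to the counts gave 1 total per library, 14.7 to 17.7 megareads. The log2 fold changes were deposited by the authors from their own fit of the first-named over the second-named group. The p-values and adjusted p-values were made by the authors, with a Benjamini-Hochberg adjustment over more genes than are listed and a value of 1 for genes left out of it. No genome build or annotation was named, so coordinates are as deposited, and genes without an entry in a table have no value there.

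The calls at the authors' adjusted p under 0.05 were the main result for each pair of groups. Levels are given as RPM, the count scaled to the total behind the FPKM values, as mean ± SD over the 2 libraries. The count error of a gene follows from its reads, and intervals between libraries cannot separate it from spread at n = 2. The 6582 genes with counts in all 8 libraries, each listed in at least one table and so selected for a change, were refitted with edgeR 4.0.16 quasi-likelihood, scaled to the same totals. This refit gave the interaction, with a Benjamini-Hochberg adjustment over these genes. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, R 4.3.3, limma 3.58.1 and DESeq2 1.42.0 were also used.

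Before the data were examined, 26 gene lists of 481 symbols were fixed, with older and newer symbols of a gene counted once in the size of a list. Of the symbols 365 were found by name, 7 by an older symbol in RefSeq, and 109 were in no table. Across lists 10 symbols stand on more than 1 list, and 0 of those are cell type markers. The lists are HIF targets, NRF2 targets, other antioxidants, aryl hydrocarbon receptor genes, glycolysis, the citric acid cycle, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, cell cycle, sarcomere, calcium and ion channels, natriuretic and stress genes, acetylation, autophagy, apoptosis, heat shock, stress signalling, inflammation and interferon. The others are markers of fibroblasts, smooth muscle, endothelium, macrophages, erythroid cells and glia. Called members were tested with an exact two-sided binomial sign test against the share of all calls that were higher, adjusted over the lists with a call. For the eugenol comparisons and the interaction, limma camera with a preset correlation of 0.01 and with an estimated one was added.

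The named genes were the 5 largest rises and 5 largest falls per comparison among called genes with a symbol (LOC, RGD, Mir and contig names left out), libraries that did not overlap and a higher mean of at least 5 RPM, up to 3 called members of each list with the smallest adjusted p, and 10 genes always named, of which the text prints a selection. Members of counts of 5 or fewer were also named, chosen after their values were seen. The relations between effects were set against 100 simulated sets with no eugenol effect, or with equal ischemia effects, which kept shared libraries. On simulated data with 6582 genes the edgeR fit recovered 74.6%, 97.0% and 100% of genes changed 1.5, 2 and 4 times, with 14 false calls and 0 calls in an unchanged pair. The 200 changed genes were drawn only from genes with a mean of at least 5 RPM, and p was adjusted over 6582 genes. The eugenol refits hold genes of lower counts and were adjusted over 18972 genes in ischemia and 14362 in normoxia. These shares therefore overstate what those refits could find. The alternatives were TMM and DESeq2 size factors, a minimum of 5 RPM, a fold minimum of 2, an adjusted p of 0.01, a fit of the 2 groups alone, DESeq2's Wald test, the replicate number as a term, and leaving out each library.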

Results

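RNA was sequenced from rat neonatal ventricular cardiomyocytes, the contractile cells of the newborn heart's main pumping chambers, kept for 24 h in normoxia or in an ischemic condition with 1% oxygen. In each condition the cells received 10 µM eugenol, a phenolic compound of clove oil that the series groups with antioxidants, or the solvent DMSO. The 4 groups, normoxia DMSO, normoxia eugenol, ischemia DMSO and ischemia eugenol, held 2 libraries each. The read totals behind the FPKM values, in M (megareads), were 16.5 and 16.1 M in normoxia DMSO, 15.5 and 14.7 M in normoxia eugenol, 17.7 and 15.9 M in ischemia DMSO, and 16.0 and 16.7 M in ischemia eugenol. The 5 deposited tables together listed 9025 genes, each table holding only the genes with an unadjusted p under 0.05 in its comparison. Nothing in the labels says that the libraries of a group came from separate isolations of cells, so each p-value measures the spread between these libraries, which can be technical. An exact permutation test of 2 against 2 libraries cannot go below a two-sided p of 0.333. Coordinates are as deposited, with no genome build named. Oxygen level below names the whole condition, since low oxygen cannot be told apart from other parts of the ischemic condition.

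Ischemia and normoxia libraries lay apart, whereas DMSO and eugenol libraries at the same oxygen level were about as alike as libraries of one group. Over 5863 genes with a mean of at least 5 RPM (reads in each library scaled to the total behind its FPKM values, as for FPKM without the gene length), Pearson's r across genes was 0.989 to 0.993 between libraries of one group, 0.989 to 0.995 between libraries of different groups at the same oxygen level, and 0.789 to 0.836 between oxygen levels. The matching Spearman's rho was 0.991 to 0.995, 0.992 to 0.996 and 0.794 to 0.842. By median absolute log2 difference the closest pair at each oxygen level crossed the treatments. It was 0.0813 between normoxia DMSO 2 and normoxia eugenol 1, against 0.132 and 0.0951 within the DMSO and eugenol groups. In ischemia it was 0.0849 between DMSO 2 and eugenol 1, against 0.101 and 0.132. By Pearson's r the closest ischemia pair was that of the DMSO libraries (0.992). Genes are not independent replicates, so these values carry no p-value, and the genes were pre-selected by the tables, most of them for a change with oxygen. The libraries of each group differed by more than sampling noise (chi-square per degree of freedom 6.68 to 15.6). The 2 libraries within a group were thus not 1 library sequenced again. Whether they were prepared from the same cells cannot be decided this way. Pairs across groups were not tested.

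The comparison of ischemia DMSO with normoxia DMSO asked what the ischemic condition changed without eugenol. Ischemia raised HIF targets, glycolysis genes and NRF2 targets and lowered genes of cell division, cholesterol synthesis, the citric acid cycle, the respiratory chain and the contractile apparatus. Hmox1, which encodes the haem-degrading enzyme haem oxygenase, rose from 54.7 ± 14.1 to 1502 ± 111 RPM (mean ± SD, n = 2 libraries per group, as for all such values). Slc2a1, the glucose transporter GLUT1, rose from 193 ± 8.69 to 1111 ± 54.7, and Acta2, smooth muscle actin, fell from 3134 ± 425 to 290.4 ± 26.7. In the authors' deposited table, 6713 genes passed an adjusted p of 0.05, 3231 higher and 3482 lower in ischemia, out of 16406 genes adjusted.

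All 21 listed members of the 25 hypoxia-inducible factor (HIF) targets were called higher, and 21 were called when adjusted over the list alone. Ndrg1, a hypoxia-responsive gene of cell differentiation, rose from 30.3 ± 0.999 to 387.7 ± 13.3 RPM (n = 2), and Vegfa, the angiogenic growth factor, from 990 ± 81.0 to 3645 ± 402. Hk2, a hexokinase that starts glycolysis, rose from 180.4 ± 28.5 to 1000.4 ± 16.2, and Pdk1, a kinase that holds back pyruvate dehydrogenase, from 135 ± 22.2 to 404 ± 13.5. Of 19 glycolysis genes 13 were called higher and 3 lower (16 adjusted over the list alone). Aldoa, an aldolase, rose from 2308 ± 80.4 to 5329 ± 60.4, while the 3 lower ones, Eno3, Ldhb and Pgam2, encode isoforms typical of muscle or heart. The sign test, an exact two-sided binomial test of the called members against the 48.1% of all calls that were higher, gave adjusted p = 5.14e-06 for HIF targets and 0.0249 for glycolysis over 24 lists.

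Of the lists of oxidant defence, the NRF2 targets rose and the other antioxidants had calls in both directions. Of 24 NRF2 targets 16 were called higher and 0 lower (18 adjusted over the list alone, adjusted p = 5.58e-05). Ftl1, the ferritin light chain that stores iron, rose from 289.7 ± 5.32 to 1869 ± 5.30 RPM (n = 2), Sqstm1, an autophagy receptor, from 225 ± 19.2 to 1074 ± 12.9, and Osgin1, an oxidative-stress growth inhibitor, from 4.03 ± 1.13 to 112 ± 7.37. Nqo1, a quinone reductase, rose from 29.3 ± 1.23 to 91.5 ± 0.855. The other antioxidant list had 4 members called higher and 7 lower of 19 (12 adjusted over the list alone, adjusted p = 0.602). Its metallothioneins rose, Mt1 from 16.9 ± 0.571 to 267 ± 2.80 and Mt2A from 13.8 ± 1.46 to 247 ± 11.3, and Txnip, an inhibitor of thioredoxin, fell from 235.8 ± 22.2 to 28.9 ± 4.80. Of 10 aryl hydrocarbon receptor and xenobiotic genes 6 were called higher and 0 lower (6 adjusted over the list alone, adjusted p = 0.0271), among them the detoxifying cytochromes Cyp1a1, from 0.245 ± 0.00493 to 10.5 ± 2.56, and Cyp1b1, from 106.8 ± 17.0 to 263 ± 1.37.

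Genes of mitochondrial energy supply fell by smaller amounts. Of 20 citric acid cycle genes 18 were called lower and 0 higher (19 adjusted over the list alone, adjusted p = 5.58e-05), as with Mdh2, malate dehydrogenase, from 635 ± 47.3 to 358.5 ± 2.23 RPM (n = 2). Of 28 oxidative phosphorylation genes 19 were called lower and 2 higher (23 adjusted over the list alone, adjusted p = 0.00106). Ndufs1, a complex I subunit, fell from 523 ± 78.1 to 289.8 ± 3.75 and Cycs, cytochrome c, from 491 ± 49.3 to 262 ± 16.2, and the 2 higher members, Esrra and Ppargc1b, are transcriptional regulators of mitochondrial genes. Of 26 fatty acid oxidation genes 13 were called lower and 3 higher (17 adjusted over the list alone, adjusted p = 0.0454), a call lost with a fold minimum of 2 (adjusted p = 0.826). Fabp3, the heart fatty acid binding protein, fell from 572 ± 70.6 to 233 ± 7.74 and Acadm, an acyl-CoA dehydrogenase, from 183 ± 22.4 to 91.5 ± 1.67.

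Sarcomere genes fell as a group, with 17 of 23 called lower and 3 higher (20 adjusted over the list alone, adjusted p = 0.00875). Actc1, cardiac actin, fell from 19946 ± 811 to 7426 ± 236 RPM (n = 2), Myl4, an atrial and fetal myosin light chain, from 254 ± 4.37 to 50.9 ± 5.79, and Myh6, the fast cardiac myosin heavy chain, from 9031 ± 318 to 6370.1 ± 1037. The 3 higher members were Acta1, Des and Myh7. Of 24 calcium handling and ion channel genes 13 were called lower and 4 higher (18 adjusted over the list alone), which did not pass the sign test (adjusted p = 0.0886). Casq2, the calcium store protein calsequestrin, fell from 1187 ± 124 to 339 ± 22.0 and Sln, a regulator of the calcium pump, from 36.2 ± 1.09 to 6.06 ± 0.753. The natriuretic peptide and stress list had 7 members called lower and 4 higher of 14 (13 adjusted over the list alone, adjusted p = 0.602). The natriuretic peptides Nppa and Nppb fell, Nppa from 21038 ± 425 to 11921 ± 531 and Nppb from 1775 ± 302 to 382 ± 75.4, and so did Ankrd1, a stretch-responsive cardiac gene, from 5230 ± 754 to 944 ± 107, while Myc, a growth-promoting transcription factor, rose from 23.8 ± 2.00 to 129 ± 20.

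All 22 listed members of the 23 cell cycle genes were called lower (22 adjusted over the list alone, adjusted p = 7.65e-06). Ccnb1, the mitotic cyclin B1, fell from 105.9 ± 9.63 to 20.6 ± 1.69 RPM (n = 2) and Rrm2, a ribonucleotide reductase subunit, from 120.8 ± 13.9 to 16.9 ± 2.33. All 17 listed members of the 19 cholesterol synthesis genes were also called lower (17 adjusted over the list alone, adjusted p = 8.75e-05). Idi1, an isomerase of the mevalonate pathway, fell from 119.5 ± 11.4 to 11.7 ± 1.39, and Hmgcs1, the HMG-CoA synthase of the same pathway, from 338 ± 30.3 to 74.7 ± 3.27. Of 30 acetylation enzymes and readers 15 were called higher and 2 lower (20 adjusted over the list alone, adjusted p = 0.00325). The higher ones included acetyltransferases, such as Crebbp from 41.9 ± 0.365 to 106.5 ± 6.78 and Ep300 from 22.2 ± 2.74 to 38.6 ± 0.574, and enzymes of the opposite activity, such as the deacetylase Hdac4 from 12.4 ± 0.336 to 24.0 ± 1.29. The 2 lower ones were Brd2 and Hdac2.

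The stress-signalling lists were mixed. Of 18 autophagy genes 10 were called higher and 3 lower (13 adjusted over the list alone, adjusted p = 0.0886), with Bnip3, a mitophagy receptor, rising from 365 ± 81.0 to 1017 ± 14.1 RPM (n = 2). The integrated stress and endoplasmic reticulum stress list had 10 of 23 called higher and 5 lower (15 adjusted over the list alone, adjusted p = 0.249). Its transcription factors Atf4, from 280 ± 13.4 to 786 ± 31.0, and Ddit3, from 40.9 ± 3.6 to 175 ± 1.82, rose, whereas the 5 lower members, Calr, Chac1, Creld2, Manf and Sdf2l1, were mostly endoplasmic reticulum proteins. Inflammation had 10 of 20 called higher and 5 lower (15 adjusted over the list alone, adjusted p = 0.249), with the chemokine Cxcl1 rising from 19.6 ± 1.64 to 62.3 ± 11.8 and the chemokine Ccl2 falling from 112.5 ± 6.67 to 42.4 ± 8.46. Heat shock and apoptosis each had 3 members called higher and 5 lower (8 adjusted over the list alone, adjusted p = 0.728), of 13 and 20 genes. The small heat shock protein gene Cryab fell from 1078 ± 91.7 to 387 ± 31.1, and the pro-apoptotic Bcl2l11 rose from 15.7 ± 1.81 to 71.0 ± 2.30. The interferon list had 1 called higher and 5 lower of 16 (6 adjusted over the list alone, adjusted p = 0.265), with the low-level Ifit3 falling from 3.43 ± 0.625 to 0.887 ± 0.101.

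Among markers of other heart cell types, those of macrophages passed the sign test, lower in ischemia, and those of fibroblasts, smooth muscle and endothelium did not. Of 14 macrophage markers 8 were called lower and 0 higher (10 adjusted over the list alone, adjusted p = 0.0217), such as lysozyme Lyz2, from 34.7 ± 3.20 to 13.3 ± 0.925 RPM (n = 2). Of 15 fibroblast markers 9 were called lower and 2, Dcn and Vim, higher (13 adjusted over the list alone, adjusted p = 0.108), with collagen Col3a1 from 3763 ± 117 to 1710 ± 66.7 and Thy1 from 90.1 ± 9.48 to 23.7 ± 0.387. Of 9 smooth muscle markers 7 were called lower and 1, Pdgfrb, higher (8 adjusted over the list alone, adjusted p = 0.108), and of 13 endothelial markers 4 were called lower and 0 higher (4 adjusted over the list alone, adjusted p = 0.178), among them Eng from 195 ± 19.1 to 82.0 ± 6.37. With 4 called members the endothelial list could not have passed (sign test, unadjusted p = 0.126). The median log2 change of listed members was -1.36 for macrophage, -1.32 for smooth muscle, -1.26 for endothelial and -0.40 for fibroblast markers. Passing or missing is therefore no test of a difference between these cell types. The erythroid and glial lists had 0 members listed in this table.

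The largest rises among called genes with a symbol other than LOC, RGD or contig names, libraries that did not overlap and a higher mean of at least 5 RPM were in Cyp1a1, Nrcam, Osgin1, Hmox1 and Clip3, with log2 fold changes of 5.42 to 4.66 in the authors' deposited table. Nrcam, a cell adhesion molecule, rose from 0.489 ± 0.164 to 17.6 ± 0.832 RPM (n = 2). The largest falls under the same limits were in Wscd2, Ogn, Tma7, Asb4 and Cd34, from -6.00 to -4.35 in the authors' deposited table. Wscd2 fell from 18.9 ± 0.727 to 0.295 ± 0.0616 and Cd34, a marker of endothelial and progenitor cells, from 21.2 ± 0.772 to 1.05 ± 0.290. Tma7 rested on uneven libraries, with 477 and 31 reads in normoxia DMSO and 20 and 3 in ischemia DMSO, and without normoxia DMSO replicate 1 its edgeR refit gave -1.50 with an adjusted p of 0.179.

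**Figure D1:**
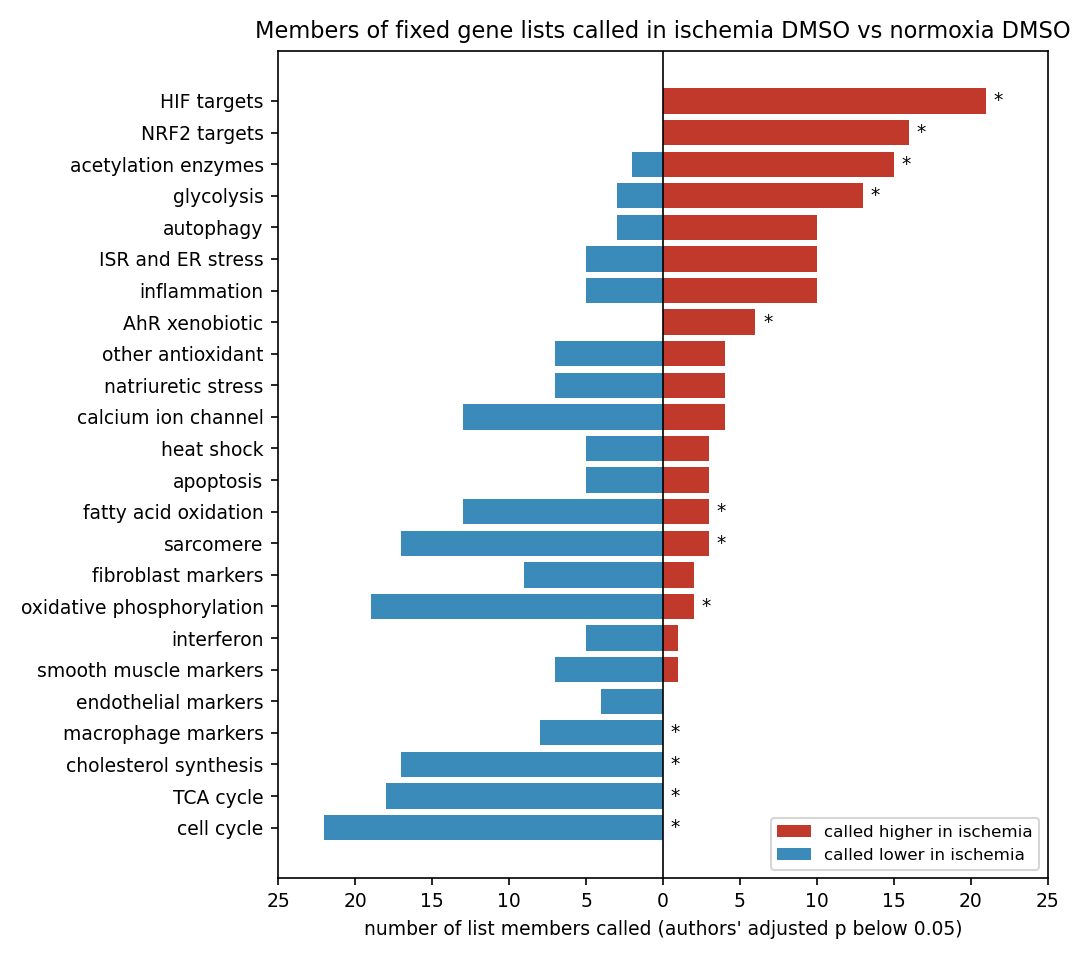
Number of members of each fixed gene list called higher (red, to the right) or lower (blue, to the left) in ischemia DMSO against normoxia DMSO at the authors' adjusted p under 0.05. A star marks lists whose sign test had an adjusted p under 0.05, from 21 higher and 0 lower HIF targets at the top to 0 higher and 22 lower cell cycle genes at the bottom.

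**Figure D2:**
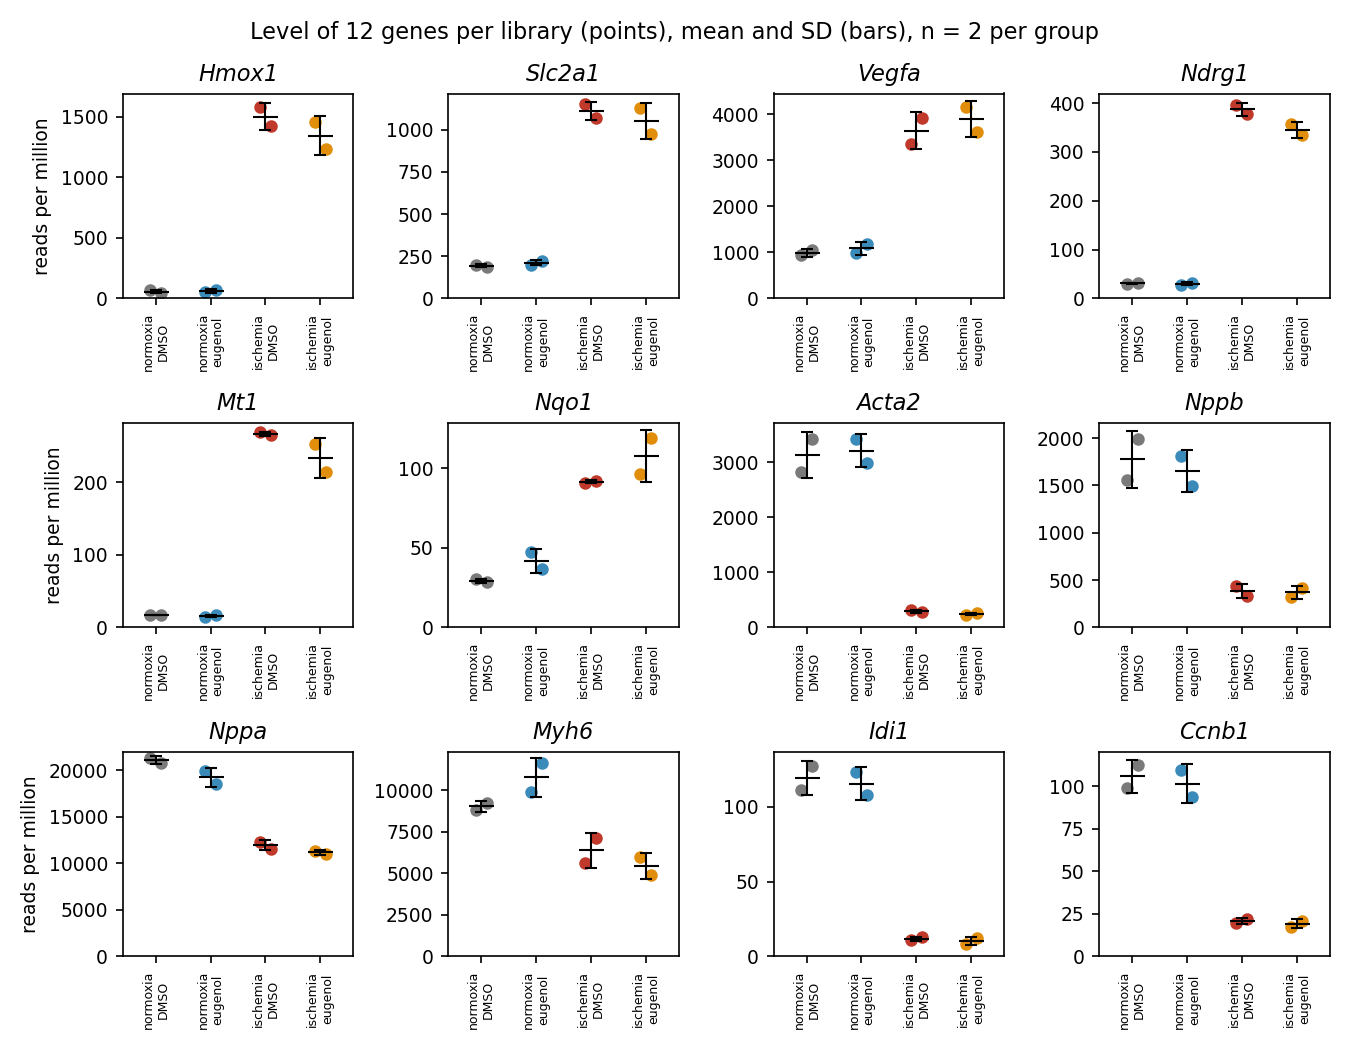
RPM of 12 genes (vertical axes, starting at 0) in each library of the 4 groups (points), with the group mean and SD (bars, n = 2). The DMSO and eugenol groups at the same oxygen level lie close together beside the distance between oxygen levels, as for Hmox1 at 1502 and 1343 RPM in the ischemia groups.

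Scaling set the zero of these changes. Over 6582 genes with counts in all 8 libraries, the median log2 fold change of ischemia DMSO against normoxia DMSO was -0.31 with the authors' totals, -0.23 with TMM and -0.08 with DESeq2 size factors, so falls of the size seen for mitochondrial genes were in part relative to that median. The majority direction of the calls depended on it: the edgeR refit called 3091 genes higher and 3379 lower with the authors' totals, and 3137 higher and 2601 lower with DESeq2 size factors. With eugenol present the same refits called 3100 higher and 3349 lower, and 3148 higher and 2556 lower. TMM gave 3128 higher and 3167 lower without eugenol, and 3138 higher and 3050 lower with it. With DESeq2 size factors the fall of Myh6 shrank to -0.27 (adjusted p = 0.170 in the edgeR refit) and lost its call, as it did without ischemia DMSO replicate 1 (-0.35, adjusted p = 0.0636). The pairs Myh6 and Myh7, and Acta2 and Actc1, are similar in sequence, and the strand of counting was not given, so reads can be shared within each pair, which was not tested. The sign tests treat list members as independent.

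The second comparison of oxygen levels, ischemia eugenol with normoxia eugenol, shared no library with the first. With eugenol present, ischemia again raised HIF and NRF2 targets and glycolysis and lowered cell cycle, cholesterol, citric acid cycle and sarcomere genes. Txnrd1, thioredoxin reductase, rose from 156 ± 4.61 to 763 ± 74.8 RPM (n = 2), Adm, the vasodilator peptide adrenomedullin, from 33.1 ± 1.14 to 200.3 ± 13.2, and Hmox1 from 60.6 ± 13.2 to 1343 ± 160. Cdc20, a mitotic checkpoint gene, fell from 119.6 ± 0.329 to 24.3 ± 0.911, Sqle, squalene epoxidase, from 157.8 ± 6.30 to 33.8 ± 2.87, and Myl7, an atrial myosin light chain, from 170.4 ± 2.37 to 39.0 ± 3.19. The authors' deposited table held 6578 genes past an adjusted p of 0.05, 3134 higher and 3444 lower, of 16021 adjusted.

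Of 24 lists tested in this comparison, 8 were shifted up and 8 down by the sign test. The NRF2 targets had 19 called higher and 0 lower (19 adjusted over the list alone, adjusted p = 9.15e-06) and HIF targets 21 and 1 (22, adjusted p = 2.19e-05). Glycolysis had 14 and 3 (17, adjusted p = 0.0139), and acetylation enzymes 13 and 1 (14, adjusted p = 0.00214). Aryl hydrocarbon receptor genes had 6 and 0 (6, adjusted p = 0.0234). Stress signalling had 11 higher and 1 lower (12, adjusted p = 0.00631), inflammation 10 and 2 (12, adjusted p = 0.0286) and autophagy 10 and 2 (12, adjusted p = 0.0286). Among their members, Ppp1r15a, a phosphatase subunit of the stress response, rose from 72.2 ± 6.93 to 202 ± 2.27 RPM (n = 2), the cytokine Lif from 6.62 ± 2.43 to 44.8 ± 2.56, and the adhesion molecule Icam1 from 57.1 ± 1.95 to 121.8 ± 3.93.

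Among the lists shifted down with eugenol present, cell cycle had 0 called higher and 22 lower (23 adjusted over the list alone, adjusted p = 9.15e-06). The others were cholesterol synthesis, 0 and 18 (18, adjusted p = 6.20e-05), and the citric acid cycle, 0 and 16 (17, adjusted p = 0.000187). Oxidative phosphorylation, 2 and 16 (19, adjusted p = 0.00476), and sarcomere, 2 and 18 (20, adjusted p = 0.00206), followed. Calcium and ion channels, 3 and 15 (19, adjusted p = 0.0190), fibroblast markers, 2 and 11 (13, adjusted p = 0.0365), and macrophage markers, 0 and 7 (8, adjusted p = 0.0286), were the last. With a fold minimum of 2 the fibroblast markers did not pass (adjusted p = 0.329). Top2a, a topoisomerase of dividing cells, fell from 231 ± 14.0 to 53.8 ± 10.8 RPM (n = 2), Col3a1 from 3972 ± 119 to 1406 ± 24.3 and Csf1r, a macrophage receptor, from 18.6 ± 0.870 to 8.14 ± 0.504. The remaining lists did not pass. Fatty acid oxidation had 5 called higher and 11 lower (16 adjusted over the list alone, adjusted p = 0.276), smooth muscle markers 1 and 7 (8, adjusted p = 0.103), and endothelial markers 0 and 4 (4, adjusted p = 0.169). With 4 called members the endothelial list could not have passed here either (sign test, unadjusted p = 0.127). Interferon genes had 1 and 4 (5, adjusted p = 0.453), and natriuretic and stress genes 4 and 7 (12, adjusted p = 0.633). Apoptosis had 3 and 5 (8, adjusted p = 0.795), heat shock 3 and 4 (7, adjusted p = 1) and other antioxidants 6 and 7 (14, adjusted p = 1). Passing in this comparison and missing in the other is no test of a difference between them, which the interaction gives.

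Among the largest rises with eugenol present, under the same limits, were those of Nrcam, Cyp1a1, Slamf7 and Pla2g7, with log2 fold changes of 5.78 to 4.67 in the authors' deposited table. Pla2g7, a phospholipase that breaks down platelet-activating factor, rose from 6.83 ± 1.80 to 173.8 ± 29.5 RPM (n = 2). The largest falls under these limits were in Wscd2, Timm17b, Cd34, Cmtm5 and Asb4, from -7.71 to -4.06 in the authors' deposited table. Wscd2 had 2 reads and 1 read in ischemia eugenol, so the size of its change is imprecise. In the edgeR refit 2 named genes lost their call when 1 library was left out: Oasl without ischemia eugenol replicate 1 (adjusted p = 0.0501) and Hdac4 without normoxia eugenol replicate 1 (adjusted p = 0.0556).

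Nearly all of the selected genes lay on the same side in ischemia with and without eugenol. The calls of both comparisons shared 2694 genes higher in both and 3021 lower in both, against 632 and 748.5 for independent lists, and 8 genes were called in opposite directions. Across the 6582 genes with counts in all 8 libraries 99.6% had the same sign, and the slope of the log2 fold changes with eugenol on those without was 0.947, against 0.968 ± 0.00517 (SD) in 100 simulated sets with equal effects. The slope was 0.962 without normoxia eugenol replicate 2, within 2 simulated SDs of the simulated 0.968 ± 0.00598, and 0.986 without ischemia eugenol replicate 2, above its simulation. The simulation holds no shifts of whole libraries, so its SD understates the chance spread. Of the 6582 genes 6515 were listed at an unadjusted p under 0.05 in both comparisons, a choice that the simulation does not model. Genes whose response was lost with eugenol are thus mostly left out, so the share and the slope do not show that the whole response was kept.

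**Figure D3:**
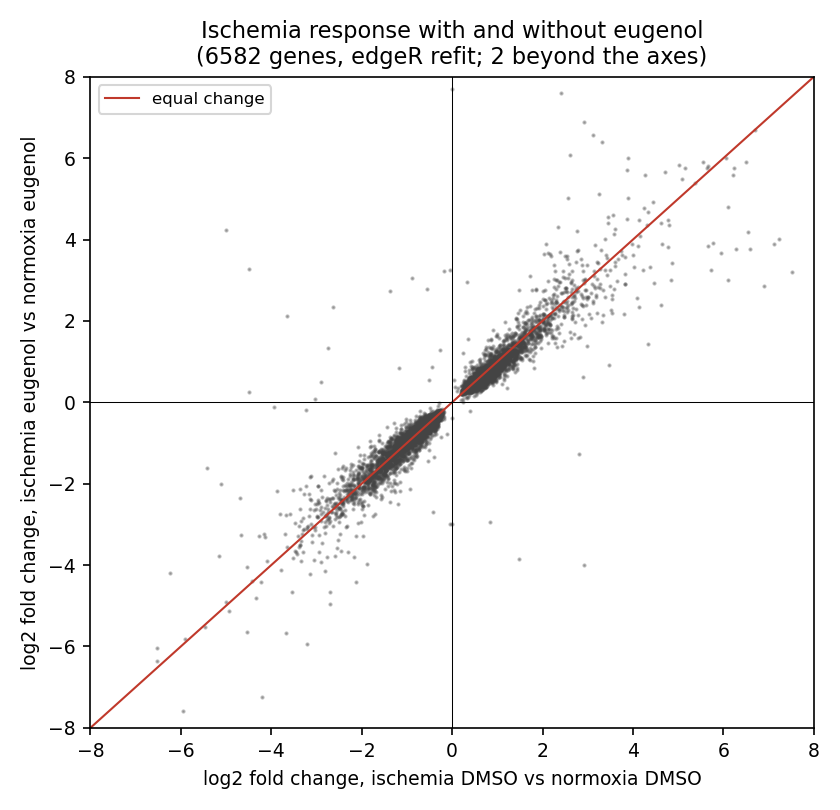
Log2 fold change of ischemia eugenol against normoxia eugenol (vertical) over that of ischemia DMSO against normoxia DMSO (horizontal) for 6582 genes (points), with the line of equal change in red. Points lie along this line, and 2 genes lie beyond the axes. Few points lie near 0 because the tables list only genes with an unadjusted p under 0.05. The slope of 0.947 given in the text comes from log2 counts with 0.5 added.

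The comparison of ischemia eugenol with ischemia DMSO asked what eugenol changed under low oxygen. Few genes changed: the authors' deposited table held 23 genes past an adjusted p of 0.05, 13 higher and 10 lower, out of 18972 adjusted. Echs1, a mitochondrial enzyme of fatty acid oxidation (chromosome 1, 212570195 to 212579057), rose from 0.683 ± 0.00985 to 23.8 ± 3.87 RPM (n = 2), and Aldh18a1, an enzyme of proline synthesis (chromosome 1, 259057402 to 259089642), from 0.414 ± 0.0526 to 6.04 ± 0.683. Pdcd5, an apoptosis-related gene (chromosome 1, 91173473 to 91178801), fell from 20.9 ± 9.54 to 0.760 ± 0.280, and Clip3, a microtubule-binding protein (chromosome 1, 90962707 to 90978907), from 24.1 ± 9.29 to 1.83 ± 0.118. Col1a2, a chain of type I collagen, fell from 1163 ± 100 to 867 ± 44.3.

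The genes with the largest rises among called genes with a symbol other than LOC, RGD or contig names, libraries that did not overlap and a higher mean of at least 5 RPM, Echs1, Aldh18a1, Hiat1, Lemd2 and Qk, had log2 fold changes of 5.13 to 1.05 in the authors' deposited table, and those with the largest falls, Pdcd5, Hiat1, Clip3, Hmgb3 and Hnrnpc, -4.77 to -0.98. Hiat1 appeared on both sides because 2 gene models carry its name. The model on chromosome 2 (219662064 to 219693629) rose from 5.61 ± 0.846 to 15.5 ± 4.01 RPM (n = 2), the model on chromosome 1 (69788609 to 69820981) fell from 10.1 ± 3.53 to 0.613 ± 0.105, and their sum was 15.7 ± 4.38 in ischemia DMSO and 16.1 ± 4.12 in ischemia eugenol, and whether reads were shared between the models was not tested. Of the 23 calls 10 had provisional names or numbers in place of a gene name (43.5%), against 8.21% of the 6713 calls for ischemia. Qk, an RNA-binding regulator of splicing, rose from 18.7 ± 0.953 to 38.4 ± 9.31.

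Of the fixed lists, fatty acid oxidation had 1 member called higher (Echs1) and fibroblast markers 1 called lower (Col1a2), with 1 and 2 members called when adjusted over the list alone. The stress signalling list had 0 called, and 1 when adjusted over the list alone. The exact sign test passed 0 lists (0 also at an unadjusted p under 0.05), and with at most 1 called member per list it could not have passed any. The camera test of the edgeR refit, which weighs all list members with counts in every library, placed fibroblast markers (median log2 -0.11, 3 of 13 higher, adjusted p = 0.000732), sarcomere genes (-0.12, 4 of 20 higher, adjusted p = 0.00120), HIF targets (-0.09, 1 of 21 higher, adjusted p = 0.00181) and smooth muscle markers (-0.16, 2 of 8 higher, adjusted p = 0.0248) lower, and fatty acid oxidation (0.05, 10 of 15 higher, adjusted p = 0.0427) higher. The mean of the fatty acid oxidation list was 0.357, most of it from Echs1 (5.10), whose counts switched between libraries in normoxia eugenol. This call may therefore rest on Echs1, and camera was not run without it, so a shift of the other members was not tested. With an estimated correlation between genes 0 lists passed, with adjusted p = 0.479, 0.307, 0.904, 0.569 and 0.904 with an estimated correlation for these 5 lists in that order. With 1 library left out, 4 of these medians differed by more than 1.5 times. For fatty acid oxidation every such median lay below that of all libraries, also without ischemia DMSO replicate 2 (0.033). That difference can therefore not be credited to single libraries. Without ischemia eugenol replicate 1 the median was -0.026 for fibroblast markers, -0.148 for HIF targets and 0.027 for fatty acid oxidation, and without ischemia eugenol replicate 2 it was -0.178, -0.047 and 0.009. Without ischemia DMSO replicate 1 it was -0.081 for smooth muscle markers and 0.022 for fatty acid oxidation, and without ischemia DMSO replicate 2 it was -0.243 for smooth muscle markers.

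The calls depended on the fit. Only 270 genes were listed at an unadjusted p under 0.05, where chance alone gives 949 of 18972. Of the 23 called genes 9 had counts in all 8 libraries, and the edgeR refit of those libraries called 1 gene, Echs1 (adjusted p = 0.0226), with 242 genes at an unadjusted p under 0.05. Col1a2, a change of -0.42 ± 0.12 (log2, SE) in that refit, had an adjusted p of 1 there. Echs1 lost this call without any 1 of the 4 ischemia libraries, with adjusted p = 0.332 and 0.614 without ischemia DMSO replicates 1 and 2, and 0.0663 and 0.118 without ischemia eugenol replicates 1 and 2, while its log2 change stayed between 4.93 and 5.26. Without ischemia DMSO replicate 2 or ischemia eugenol replicate 2 the refit called 0 genes (232 and 220 at an unadjusted p under 0.05).

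The comparison of normoxia eugenol with normoxia DMSO asked what eugenol changed at normal oxygen. The authors' deposited table held 26 genes past an adjusted p of 0.05, 11 higher and 15 lower, out of 14362 adjusted. Col1a2 rose from 1525 ± 188 to 2191 ± 373 RPM (n = 2), and Myh7, the slow cardiac myosin heavy chain, from 4594 ± 622 to 6071 ± 159. Ogn, a small proteoglycan of connective tissue, fell from 5.42 ± 0.455 to 0.303 ± 0.246, Brd2, a reader of acetylated histones, from 11.5 ± 7.77 to 2.48 ± 0.144, and Gstm5, a glutathione transferase, from 10.6 ± 0.263 to 0.427 ± 0.219. Nqo1, at 29.3 ± 1.23 and 41.8 ± 7.58, did not pass, with an adjusted p of 1.00 in the authors' deposited table.

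The largest rises among called genes with a symbol other than LOC, RGD or contig names, libraries that did not overlap and a higher mean of at least 5 RPM were in Rtkn, Tsen34, Col1a2 and Myh7, with log2 fold changes of 2.95 to 0.40 in the authors' deposited table, and the largest falls in Gstm5, Ogn, MGC94199, Wdr77 and Tmco3, from -4.63 to -3.24. Tsen34, a subunit of the tRNA splicing endonuclease (chromosome 1, 64024240 to 64030175), rose from 2.97 ± 0.157 to 10.7 ± 4.47 RPM (n = 2), and Tmco3 (chromosome 16, 81549204 to 81583916) fell from 7.22 ± 2.10 to 0.769 ± 0.356. Gstm5 belongs to a family of similar genes, so its reads may have been divided between copies, which was not tested. Myh7 lies beside its near-identical copy Myh6, which had 8806 and 9255 RPM in normoxia DMSO and 9916 and 11609 in normoxia eugenol. That both rose argues against reads moving from Myh6 to Myh7, although sharing of reads between them was not tested. Of the 26 calls 10 had provisional names (38.5%).

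Of the fixed lists, sarcomere and natriuretic stress genes (both through Myh7) and fibroblast markers (Col1a2) each had 1 member called higher, and acetylation enzymes 1 lower (Brd2). Adjusted over the list alone the counts were 1, 1, 1 and 2, with 1 in the aryl hydrocarbon receptor list, which had 0 calls, and 0 lists passed the exact sign test (0 also at an unadjusted p under 0.05), which could not pass any with at most 1 called member per list. By limma camera on the refit, NRF2 targets (median log2 0.08, 17 of 19 higher, adjusted p = 0.0187) and fibroblast markers (0.08, 9 of 13 higher, adjusted p = 0.0322) lay higher, and oxidative phosphorylation (-0.09, 2 of 19 higher, adjusted p = 0.00310), the citric acid cycle (-0.06, 1 of 17 higher, adjusted p = 0.00466), inflammation (-0.18, 2 of 12 higher, adjusted p = 0.00956) and macrophage markers (-0.22, 2 of 9 higher, adjusted p = 0.0221) lower. None of these 6 passed with an estimated correlation, where each had adjusted p = 0.700 with an estimated correlation. Without normoxia DMSO replicate 1 the medians of oxidative phosphorylation and the citric acid cycle turned to 0.017 and 0.021, and without normoxia DMSO replicate 2 they were -0.202 and -0.200. The citric acid cycle had -0.027 and -0.111 without normoxia eugenol replicates 1 and 2. Without normoxia DMSO replicate 1 the medians were also 0.049 for fibroblast markers, -0.085 for inflammation and 0.124 for NRF2 targets. The table listed 207 genes at an unadjusted p under 0.05, where chance gives 718 of 14362, and of the 26 called genes 14 had counts in all 8 libraries. The edgeR refit of those called 3 genes, Ogn among them (adjusted p = 0.0165), with 274 at an unadjusted p under 0.05, and 1 gene without normoxia eugenol replicate 1, where Ogn had -3.49 and an adjusted p of 0.196.

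**Figure D4:**
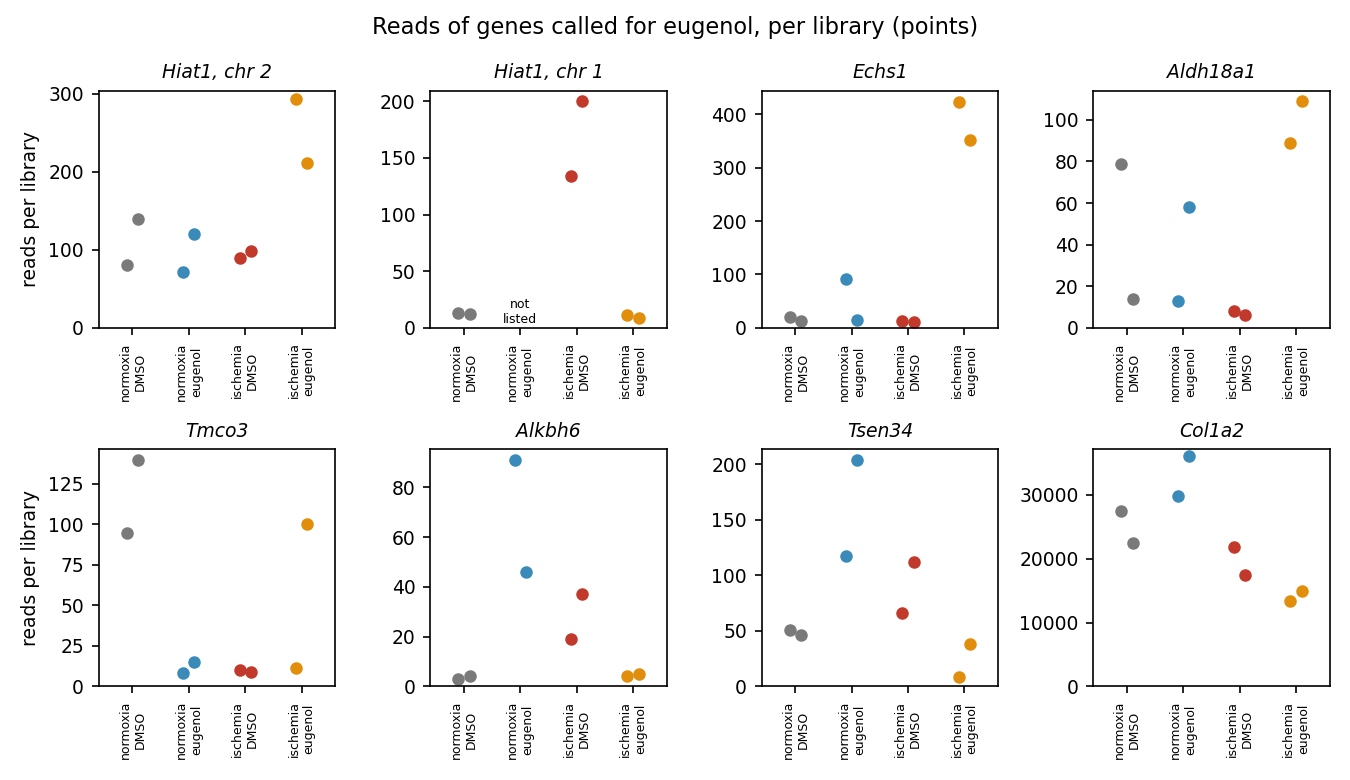
Reads per library (points, vertical axes starting at 0) of 8 gene models called for eugenol in at least one comparison, in the 4 groups. Counts switch between low and high values, also between libraries of one group, as for Tmco3 with 11 and 100 reads in the ischemia eugenol libraries and Echs1 with 91 and 14 in the normoxia eugenol libraries, while Col1a2 shifts at a high count.

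The interaction asked whether eugenol acted differently in ischemia and normoxia. It was tested on genes that the tables had listed for a change in the same libraries. Most were listed in both comparisons of ischemia with normoxia, and the interaction is the difference of those effects. Its adjusted p-values, for genes and for lists, do not allow for this choice. Alkbh6, a member of a family of oxygen-dependent demethylases (chromosome 1, 90957133 to 90962466), was the 1 gene that passed among the 6582 genes, with a difference of eugenol effects of -6.92 ± 0.82 (log2, SE, edgeR quasi-likelihood, adjusted p = 0.0122). Its reads were 3 and 4 in normoxia DMSO, 91 and 46 in normoxia eugenol, 19 and 37 in ischemia DMSO, and 4 and 5 in ischemia eugenol. With a minimum mean of 5 RPM, which removes this gene, the edgeR fit called 0 genes (195 at an unadjusted p under 0.05), and DESeq2's Wald test called 5. The next genes, AABR07029056.1, Rbm12, Col1a2 (-0.95 ± 0.17) and Tmco3, each had an adjusted p of 0.143 in the edgeR fit, and 236 genes had an unadjusted p under 0.05. Leaving out 1 library moved the count from 1 to between 0 (without ischemia DMSO replicate 2 or ischemia eugenol replicate 2) and 9 (without normoxia DMSO replicate 2). It was 7 without normoxia DMSO replicate 1, 4 without ischemia DMSO replicate 1, 3 without normoxia eugenol replicate 1 or ischemia eugenol replicate 1, and 2 without normoxia eugenol replicate 2.

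By limma camera, fibroblast markers (median difference -0.22, adjusted p = 1.08e-05), sarcomere genes (-0.12, adjusted p = 0.000229), HIF targets (-0.12, adjusted p = 0.0311) and smooth muscle markers (-0.14, adjusted p = 0.0322) had lower eugenol effects in ischemia than in normoxia, and inflammation (0.24, adjusted p = 0.000933) and fatty acid oxidation (0.07, adjusted p = 0.0491) higher ones. The mean of the fatty acid oxidation list was 0.264, most of it from Echs1 (3.34). With an estimated correlation 0 of the 6 passed (adjusted p = 0.268, 0.221, 0.885, 0.668, 0.668 and 0.885 with an estimated correlation, in that order). The median of fatty acid oxidation turned to -0.056, -0.021 and -0.015 without normoxia DMSO replicate 1, normoxia eugenol replicate 1 and ischemia DMSO replicate 1. It was 0.196, 0.130 and 0.043 without normoxia DMSO replicate 2, normoxia eugenol replicate 2 and ischemia eugenol replicate 1. The median of smooth muscle markers was -0.018 and -0.346 without normoxia DMSO replicates 1 and 2, -0.089 and -0.285 without normoxia eugenol replicates 1 and 2, and -0.218 without ischemia DMSO replicate 2. That of HIF targets was -0.219 and -0.031 without normoxia eugenol replicates 1 and 2, that of inflammation 0.437 and 0.120 without ischemia DMSO replicates 1 and 2, and that of fibroblast markers -0.143 without ischemia eugenol replicate 1.

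Whether eugenol moved ischemia-changed genes back was asked by setting its effect in ischemia against the effect of ischemia. Among the 6582 genes, 6515 were listed in both comparisons of ischemia with normoxia, without and with eugenol. A gene that eugenol returned to its normoxia level would tend to be missing, as was Clip3, without a value in normoxia eugenol. The relation therefore cannot count genes moved fully back. Among 10 genes called both for ischemia and for eugenol in ischemia, 8 went in opposite directions, though these effects share the ischemia DMSO libraries. Of the 6582 genes 54.4% moved in the opposite direction, against 50.2 ± 0.62% (SD) in simulated unchanged eugenol groups that shared the ischemia DMSO libraries. The covariance was -0.0269, against -0.0253 ± 0.0072 (SD) simulated, a difference of -0.00163 that lay within the simulated spread. With the ischemia DMSO libraries divided between the effects, the difference from simulation in covariance was -0.000646 for one division and 0.00279 for the other, both within the simulated spread. The share moving oppositely was 56.0% (49.9 ± 0.68% simulated, SD) and 52.9% (50.1 ± 0.64% simulated, SD), above simulation in both, though the simulation holds no shifts of whole libraries. A single library set the direction: without ischemia eugenol replicate 1 the difference was -0.0693 and 63.5% of genes moved oppositely, and without ischemia eugenol replicate 2 it was 0.0661 and 41.6%. It was also above 0 without normoxia DMSO replicate 1 (0.000923) or ischemia DMSO replicate 2 (0.00303).

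The eugenol effects in ischemia and in normoxia share no library. Across the 6582 genes 53.9% had the same sign, against 50 ± 0.62% (SD) simulated, and Pearson's r across genes was 0.079. Without ischemia DMSO replicate 1 the share was 49.1%. The calls shared 2 genes, against 0.0416 for independent lists: the provisional LOC100911994 was lower in both, and Col1a2 rose in normoxia and fell in ischemia.

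The last table set ischemia eugenol against normoxia DMSO, which combines both treatments. It held 6299 genes past an adjusted p of 0.05 in the authors' deposited table, 2971 higher and 3328 lower of 16036 adjusted. Cyp1a1 rose from 0.245 ± 0.00493 to 14.3 ± 3.50 RPM (n = 2), Slamf7, an immune receptor, from 0.182 ± 0.170 to 7.23 ± 2.94, and Hmox1 to 1343 ± 160. Timm17b, a subunit of the mitochondrial import machinery, fell from 11.4 ± 5.45 to 0.247 ± 0.180, and Wscd2, Ogn, Cd34 and Cmtm5 had the other largest falls under the limits given above. Of 25 lists 7 were shifted up and 7 down by the sign test. HIF targets (21 higher, 0 lower, 22 adjusted over the list alone, adjusted p = 3.50e-06) and NRF2 targets (19 and 0, 19, adjusted p = 7.87e-06) led the rises and cell cycle (0 and 21, 22, adjusted p = 1.38e-05) the falls. Tek lost its refit call without ischemia eugenol replicate 1 (adjusted p = 0.0569), and Oasl without that library (adjusted p = 0.0872) or without normoxia DMSO replicate 1 (adjusted p = 0.103). Fibroblast markers had 2 higher and 10 lower (15, adjusted p = 0.0704) and macrophage markers 0 and 9 (9, adjusted p = 0.0121).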

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

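Only the tests that asked whether 1 library decides a pattern were written before their result was seen; all other tests below were chosen after it. The interaction test, on genes already selected for a change, set apart 1 gene and 6 lists whose eugenol effect differed between ischemia and normoxia. For Alkbh6 the difference was -6.92 (log2). For the medians of the lists it was -0.22 in fibroblast markers, -0.12 in HIF targets, -0.12 in sarcomere genes, -0.14 in smooth muscle markers, 0.24 in inflammation and 0.0728 in fatty acid oxidation, and 0 of these lists passed with an estimated correlation.

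The first pattern is the set of genes called for eugenol, many with counts that switch between low and high. In groups outside the comparison, the libraries of one group differed by a median ratio of 1.37 for these genes, against 1.14 for expression-matched genes, the percentile being 100, and 19 of 62 values were at least 2 times apart. The called genes thus varied more between libraries of one group than matched genes did, although the ischemia eugenol libraries alone lay at percentile 26.2 for the normoxia calls. Reads switching between copies or overlapping gene models may account for part of this spread. Other sources of spread between libraries would give the same values, and the placing of reads was not examined. For an effect of eugenol alike in both oxygen conditions, the change in the other condition was -0.118 times the called one (95% interval -0.405 to 0.0987). This cannot decide the question, because genes picked for a large change in 1 condition tend to show less in the other. Being listed between the 2 eugenol groups can also favour unequal effects. Col1a2 and LOC100911994, called in both conditions, entered the interval more than once. In normoxia 1 of the 2 splits that mix DMSO and eugenol libraries called 7 genes against 1 for the real split. It had 596 genes at an unadjusted p under 0.05 (edgeR). The other mixed split called 0 (104 genes at an unadjusted p under 0.05, against 235 in the real one). Spread between libraries of one group can therefore give as many calls as the real split. Differences between replicates correlated between groups at -0.216 (normoxia DMSO and normoxia eugenol) to 0.139 (normoxia DMSO and ischemia eugenol). These values carry no test, so whether the samples hold a structure was not decided. In ischemia the real and both mixed splits gave 0 (edgeR, unadjusted p under 0.05 for 216 genes in the real split, 345 and 333 in the mixed ones), which decides nothing.

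The second pattern is the fibroblast markers, lower with eugenol in ischemia than in normoxia. Against 1 library deciding it, the median stayed at or below -0.143 with each of the 8 libraries left out in turn. A lower share of fibroblasts stays open. The markers changed unequally with eugenol in ischemia (chi-square p = 0.0279), but this test treats genes of the same libraries as independent. Unequal changes also do not exclude a lower share, since single markers can change beside it. A first version of this test, on sarcomere genes, found those lower too (median -0.118, 95% interval -0.174 to -0.0285). An abundance trend between libraries stays open as well: the median lay at percentile 0.02 of matched lists, whose range was -0.109 to 0.0356, but its bootstrap interval overlapped that range. An effect of eugenol on these genes therefore remains a hypothesis.

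The third pattern is the NRF2 targets, higher with eugenol in normoxia (median 0.08, 17 of 19 members higher), a camera call that was lost with an estimated correlation (adjusted p = 0.700). Against 1 library deciding it, the median was at least 0.0550 with each of the 4 normoxia libraries left out in turn. An abundance trend stays open, at percentile 97.92 of matched lists (range -0.0480 to 0.0733). Whether eugenol acted alike in ischemia stays open as well, since the median there was 0.00607 (95% interval -0.0491 to 0.0563), which holds both 0 and an effect of more than 0.5 of that in normoxia.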

How the results depend on the processing

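A fold minimum of 2 left 2687 genes for ischemia DMSO against normoxia DMSO, 2570 for ischemia eugenol against normoxia eugenol and 2594 for ischemia eugenol against normoxia DMSO, because it removes small changes, and 7, 10 and 7 lists in place of 12, 16 and 14. All 3 lost acetylation enzymes, aryl hydrocarbon receptor genes, macrophage markers, oxidative phosphorylation and the citric acid cycle; the first also lost glycolysis and fatty acid oxidation and gained autophagy and calcium and ion channels, the next lost fibroblast markers, and the last lost glycolysis and calcium and ion channels. Other fits and scalings gave counts within 1.5 times. With DESeq2 size factors, however, more genes were called higher than lower in all 3, the reverse of the main result. TMM reversed it for ischemia eugenol against normoxia eugenol (3138 higher, 3050 lower) and against normoxia DMSO (3128 and 3094). It did not for ischemia DMSO against normoxia DMSO (3128 and 3167). The eugenol comparisons depended on the fit. For ischemia eugenol against ischemia DMSO the 23 calls became 1 in the edgeR refit of all 8 libraries, with TMM, with DESeq2 size factors and with a minimum of 5 RPM, 11 with only the 2 groups and 6 with DESeq2's Wald test, and 0 to 1 without single libraries. For normoxia eugenol against normoxia DMSO the 26 calls became 3, 3, 3, 0 (231 at an unadjusted p under 0.05), 13 and 9 in that order, and 1 to 4 without single libraries. The interaction gave 0 genes at an adjusted p of 0.01, 0 with a minimum of 5 RPM, 5 with DESeq2's Wald test and 0 to 9 without single libraries. The refits hold fewer genes, 9 of the 23 and 14 of the 26 called; beyond that the cause was not tested.

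For the eugenol lists the sign test passed 0, and could pass none with at most 1 called member each. Camera with a preset correlation passed 5 in ischemia, 6 in normoxia and 6 in the interaction, and with an estimated correlation 0 in each. With the replicate block the edgeR refit called 1 gene in ischemia, 3 in normoxia and 2 in the interaction, and camera passed 5 and 6 lists with a preset correlation and 0 with an estimated one (smallest adjusted p = 0.569 in ischemia and 0.501 in normoxia); in the ischemia comparisons its sign tests passed 15 lists each. Without eugenol, fatty acid oxidation lost its call (adjusted p = 0.136), while autophagy (0.0312), calcium and ion channels (0.0370), inflammation (0.0312) and stress signalling (0.0312) passed. With eugenol fibroblast markers lost theirs (0.0605), and inflammation passed for ischemia eugenol against normoxia DMSO (0.0292). These calls come from the edgeR refit, so refit and block were not told apart; the numbers do not pair the samples by any label. The difference from simulation in the covariance of the eugenol effect with the ischemia effect changed sign with the other division of the ischemia DMSO libraries (0.002795, within the simulated spread), while the share of genes moving oppositely stayed above simulation (52.9% against 50.1%). The difference ran from -0.06932 to 0.06605 without single libraries. The share of eugenol effects of the same sign ran from 49.06 to 55.67%. The slope of the ischemia effects was 0.875 with one division of the libraries, below its simulated 0.941, and 0.9632 with the other, above its simulated 0.940, and 0.9077 to 0.9863 without single libraries; the cause was not tested. Named genes kept their direction under each alternative run. TMM, the refit of all 8 libraries, camera in the eugenol comparisons and the relations without single libraries were chosen after seeing the data. A fit of 2 groups cannot give the interaction, and no deposited table holds it. No filter is what the refit already used, so these alternatives were not run. The relations added a count of 0.5 before the log, and other added counts were not run. Quantile normalization and an estimated correlation for the sign tests were not run either. Without a library, the lone one was assumed to vary like the other groups.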

Other observations

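Libraries of one group lay apart along the axis that separates oxygen levels. The first principal component held 93.3% of the variance over 5863 genes, and the ischemia eugenol libraries stood at 45.3 and 37.4, with the ischemia DMSO libraries at 41.5 and 41.6 between them. The normoxia DMSO libraries stood at -40.7 and -43.2 and the normoxia eugenol libraries at -42.8 and -39.2. The 10 most abundant genes took 12.5 to 12.8% of the reads in shared genes in normoxia and 9.16 to 9.89% in ischemia.

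Clip3 and Alkbh6 lie next to each other on chromosome 1. Clip3 had 11 and 20 reads in normoxia DMSO, 545 and 280 in ischemia DMSO, and 28 and 32 in ischemia eugenol, and no value in normoxia eugenol. Alkbh6 had 3 and 4, 19 and 37, and 4 and 5 reads in the same groups.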
